A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

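RNA was measured in 18 libraries of 1 diploid hybrid, 3 independent cultures at 6 times each. Per the labels' protocols, poly(A) RNA was selected, fragmented and made into barcoded libraries with a TruSeq RNA v2 kit, which does not mark strand, and all libraries were sequenced in 1 lane as paired reads of 50 bp. So reads of overlapping genes on opposite strands cannot be told apart, and no split by lane was possible.

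The values are counts of reads per SNV and allele, deposited without normalization. Per the file headers, the authors aligned reads separately to the BY and the RM genome, removed duplicates, and counted reads at SNVs inside transcript features that include untranslated regions. Also per the file headers, overlapping genes were consolidated into 1 feature, poorly mapping SNV sites were masked and indels were removed. BWA 0.5.9, Picard 1.43 and the genome build sacCer3 are named in the submitters' processing notes. A deposited table of the whole series holds counts for 30497 of the 35952 SNVs of the tables per library. Its counts were identical to theirs at each shared SNV. How the other 5455 SNVs, with 9.82% of all allelic reads, were left out is not given in the sources used here. The table of the whole series was used for the main results and all SNVs were used as an alternative. A read that covers several SNVs can be counted at each of them. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

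Groups and replicate numbers were taken from the sample titles. Feature names were matched to gene symbols and coordinates of the R64 reference annotation, the assembly that sacCer3 stands for; positions are those of the annotated genes of a feature and are 1-based. A gene was taken to have a near-identical copy where blastn 2.17.0 found another annotated gene with at least 90% identity over at least 100 bp. SNV positions were not used here, only their index.

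Counts of the SNVs of a feature were summed per allele and library. Genes with a mean of at least 20 allelic reads per library were tested, for the ASD test with at least 2 of each allele. ASD was tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F-test on 36 allele columns, with a term for each library, a term for allele and an allele by time term linear in minutes. Both columns of a library had its total as size. The slope was multiplied by 42 min, and the adjusted p is that of Benjamini and Hochberg over the genes tested, with a threshold of 0.05. ASE at 0 min used the same test on the 6 allele columns of 3 libraries, with terms for library and allele. Abundance used the sum of both alleles with TMM factors and time as a factor of 6 levels in edgeR, and the contrast of 42 against 0 min. CPM values are means over the 3 libraries of a time. Gene lists were tested for abundance with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and for ASD with two-sided Fisher's exact tests. Lists used single-gene features only. Percentages of BY reads are means and SD of the 3 libraries of a time. Other tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

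The tests, the 16 gene lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison and direction, the 10 genes with the largest change among those passing the threshold, with the same direction in each of the 3 cultures and a mean of at least 100 reads, and for ASD at least 20 reads of each allele. It added the 3 called members of each list with the largest change, and LYS2, LEU2, URA3, RPO21, HAP1, AMN1, GPA1, IRA2 and MKT1. LEU2 and URA3 held no SNVs in the tables used and GPA1 had too few reads. Other list members, the largest genes with 10 to 90% BY reads, the segments and the genes of the closing observations were named after their values were seen.

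Each pair of libraries of one time was compared to look for a library deposited more than once, and none was found (chi-square per degree of freedom from 1.35 to 8.61, a value that reads counted at several SNVs also raise). Per the labels the cultures are independent, and aliquots of one culture were taken at each time, so the replicate numbers pair the libraries. Deviations from the time means correlated between libraries of the same number with a median of 0.165 for log2 CPM (from -0.024 to 0.508, 45 pairs), against -0.065 for different numbers, and with a median of 0.011 for log2(BY/RM). The replicate block was run as an alternative for this reason.

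The scripts were tested on simulated counts with the gene means and library sizes of the real data and 200 changed genes per test. The spread between libraries was set by hand and not fitted to the real libraries, and ASE was simulated around equal alleles, so the rates below hold for that spread only. Among 2808 genes, the ASD test recovered 28% of changes of 0.5 and 74% of changes of 1 on the log2 scale, with 2.9% false calls among calls. For ASE among 2749 genes these values were 65%, 91% and 8.2%, and for abundance among 2808 genes they were 55%, 97% and 4.4%. The absence of a call does not show equal decay.

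Alternatives covered allele totals scaled by TMM, read minimums, SNV filters, DESeq2 1.42.0, logistic regressions, limma on culture slopes, other codings of time, the replicate block, leaving out each replicate, other scalings and estimated correlations. Features of several genes and genes with near-identical copies were kept and marked as uncertain. The planned thinning of SNVs by distance was not run. The planned correlation across genes of the allelic difference at 0 min with the later change is not reported here.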

Results

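The series followed allele-specific mRNA decay in a diploid hybrid of budding yeast, Saccharomyces cerevisiae. The hybrid was made by mating the laboratory strain BY4716 (BY), a relative of the reference strain S288C, with the vineyard strain RM11-1a (RM). Both parents carried rpb1-1, a temperature-sensitive mutation in RPO21, the gene for the largest subunit of RNA polymerase II. Hot medium took the culture to the non-permissive temperature, at which transcription by this polymerase is inhibited. Poly(A) RNA was sequenced at the shift (0 min) and at 5 later times up to 42 min (6, 12, 18 and 24 min between), in 3 independent cultures (replicates 1 to 3), each sampled at every time. The 18 libraries held 13626796 reads that could be assigned to one parent at a single-nucleotide variant (SNV), here called allelic reads. Library totals ran from 439453 to 1180513, apart from the library of 18 min replicate 3, which held 74320. The reads fell on 30497 SNVs in 3974 transcript features, with a median of 4 SNVs per feature and 134 reads per SNV over all libraries. Of these features, 3055 held 1 reference gene, 856 held 2 or more overlapping genes and 63 matched no reference gene, and a value for a feature with several genes cannot be given to any one of them.

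Reads from both parents were present in nearly equal numbers in each library. The BY share of allelic reads was 49.4% ± 0.012 at 0 min and 49.6% ± 0.064 at 42 min (SD, n = 3), and all libraries lay between 49.4% and 49.6%. The difference of 0.157 percentage points gave an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give when they are not paired. Within cultures 1 to 3 the difference was 0.216, 0.0900 and 0.164 percentage points. The sign of the mean difference changed when SNVs with under 2% or over 98% BY reads were left out (-0.052 percentage points, and negative in each culture). Taken by chromosome and library, the BY share ranged from 47.0% to 54.0%, and no chromosome had lost the reads of either parent. LYS2, which encodes alpha-aminoadipate reductase of lysine synthesis and is deleted in BY4716, served as a check of the labels. Its BY share at 0 min was 0.609% ± 0.529 (SD, n = 3).

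The first comparison asked which transcripts were lost at different rates from the BY and the RM allele, seen as a change of the BY share of a gene over the time course. Such allele-specific decay (ASD) was called for 188 of 2808 genes tested (6.70%) at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The BY share rose for 102 of them, named here as the RM transcript falling faster, and fell for 86, named as the BY transcript falling faster. Among the genes with rising BY share were HAP1, a heme-responsive transcription factor, RPI1, a putative transcriptional regulator linked to Ras signalling, and HSL1, a kinase of the morphogenesis checkpoint. Among those with falling BY share were CIN5, a transcription factor of the osmotic and salt response, EXG1, a glucanase of the cell wall, and YHB1/MIC26, a feature that holds the nitric oxide dioxygenase gene YHB1 and a second gene. Changes below are of log2(BY/RM) over 42 min. The ± of a log2 value, here and below, is the value divided by the square root of its F statistic. It stands in for a standard error, and is too small where an allele or a time has very few reads.

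YPL088W, a putative aryl alcohol dehydrogenase gene (chromosome XVI, 381965 to 382993), had the lowest adjusted p, with a change of 3.04 ± 0.17 (adjusted p = 4.98e-24). Its BY share went from 15.5% ± 3.11 at 0 min to 55.7% ± 6.92 at 42 min (SD, n = 3). RPI1 (IX, 136654 to 137877) changed by 2.98 ± 0.29, from 47.2% ± 6.68 to 82.6% ± 8.27 BY reads. HAP1 (XII, 646415 to 650923) changed by 1.62 ± 0.17, from 62.7% ± 4.62 to 84.4% ± 1.27. ATM1, which encodes a mitochondrial transporter needed for cytosolic iron-sulfur proteins, changed by 1.49 ± 0.20. RDL1, a thiosulfate sulfurtransferase gene, changed by 1.14 ± 0.11, from 22.5% ± 2.63 to 41.3% ± 1.66. ATG19, which encodes a receptor of the Cvt pathway, changed by 1.09 ± 0.16 and HSL1 (XI, 248920 to 253476) by 1.05 ± 0.10. The feature PET54/HSV2 changed by 0.98 ± 0.17. ERC1, a transporter of the multidrug and toxin extrusion family, changed by 0.98 ± 0.24, and its call was lost without replicate 2 (adjusted p = 0.053) and without replicate 3 (adjusted p = 0.112). DBP2, an RNA helicase gene, had the largest estimate, 3.31 ± 0.67 (adjusted p = 2.48e-04). Its reads had almost gone from 18 min on, so this value rests on the libraries of 0 to 12 min, and without those of 0 min it was 1.56 (adjusted p = 0.589).

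In the other direction, URA7, given below, had the largest change of the 10 genes taken by the naming rule, followed by CIN5. CIN5 (XV, 383533 to 384420) changed by -1.75 ± 0.17 (adjusted p = 2.02e-13), from 88.0% ± 6.12 to 58.2% ± 6.53 BY reads (SD, n = 3). EXG1 (XII, 728955 to 730301) changed by -1.73 ± 0.16, from 65.7% ± 1.48 to 33.7% ± 4.17, and stood at 49.1% ± 1.95 by 6 min. YDL124W, an aldo-keto reductase gene (IV, 240259 to 241197), changed by -1.47 ± 0.11, from 81.4% ± 2.33 to 57.5% ± 2.08. CIN5 had a mean of 121 reads per library at 0 min and 569 over all 18 libraries, and YDL124W 569 and 1589. A falling BY share of these 2 genes thus need not be faster loss of the BY transcript. The feature YHB1/MIC26 (VII, 959904 to 962061) changed by -1.37 ± 0.10, from 50.5% ± 1.31 to 28.8% ± 8.44, and YLR177W, of unknown function, by -1.13 ± 0.15. GPP1, a glycerol phosphatase gene read at 1 SNV, changed by -1.58 ± 0.26. The feature INA1/PUN1/YLR415C changed by -1.57 ± 0.26, and its 42 against 0 min difference alone did not pass (-0.59, adjusted p = 0.343). It also did not pass without the 0 min libraries (-0.21, adjusted p = 0.826), with all SNVs (-0.48, adjusted p = 0.0567) or in DESeq2 (-0.86, adjusted p = 0.156). URA7, which encodes a CTP synthase, changed by -1.91 ± 0.44, but few of its reads were left at 42 min. The SD of its BY share was 25.6 percentage points there. URA7 did not pass with time as a factor (-1.32, adjusted p = 0.168) or with the deepest SNV (-2.01, adjusted p = 0.119). ENA1, a sodium pump gene with the near-identical copies ENA2 and ENA5, changed by -1.30 ± 0.27 and is uncertain for that reason. Its BY share fell mostly by 6 min, from 95.5% ± 2.02 to 76.0% ± 4.12, and was 70.7% ± 3.24 at 42 min (SD, n = 3), and without the 0 min libraries the change did not pass (-0.31, adjusted p = 0.577). MTR4, an RNA helicase of the nuclear exosome, changed by -1.07 ± 0.32 (adjusted p = 0.0244). Without replicate 3 the change was -0.91 for ENA1 (adjusted p = 0.104) and -0.74 for MTR4 (adjusted p = 0.388), and without replicate 1 MTR4 had an adjusted p of 0.170. MTR4 also did not pass without the libraries of 0 min (adjusted p = 0.167) or 42 min (adjusted p = 0.207) or with time as a factor (adjusted p = 0.142), and its sign turned with the deepest SNV (0.29, adjusted p = 0.965).

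**Figure D1:**
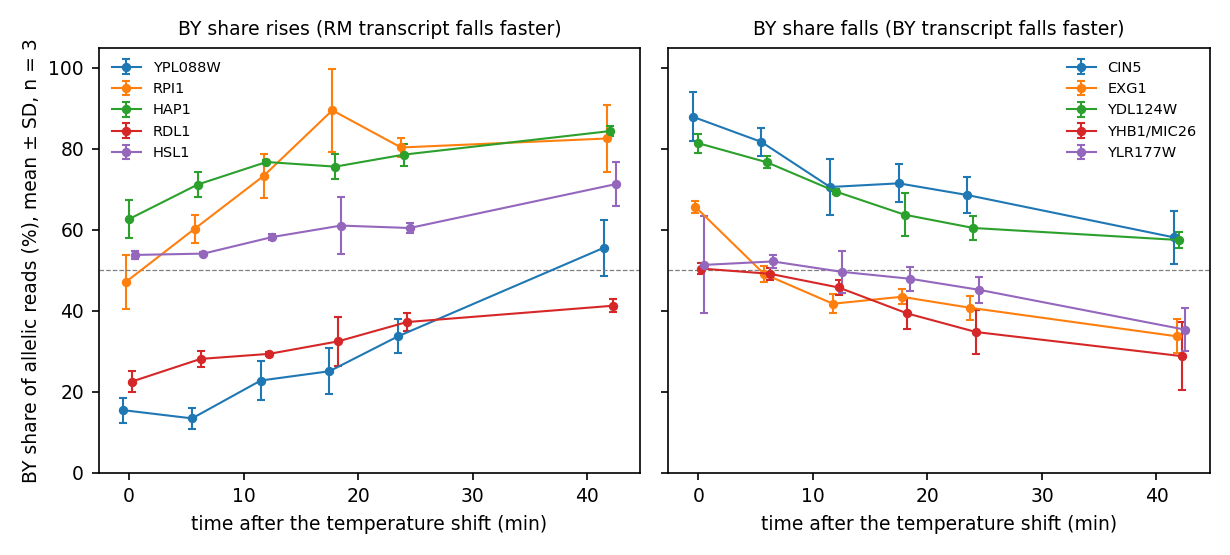
BY share of allelic reads in percent (vertical axis) against minutes after the temperature shift (horizontal axis), as the mean ± SD of 3 cultures, for 5 genes whose BY share rose (left) and 5 features whose BY share fell (right). Points at one time are set slightly apart sideways so that bars do not overlap. The mean of YPL088W rises from 15.5% to 55.7%, and that of CIN5 falls from 88.0% to 58.2%. Panel titles name the direction only, since a share can also change through unequal new transcription after the shift.

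None of the 14 fixed gene lists tested held more ASD genes than the other genes after adjustment over the lists. The list nearest to it was that of regulators known to be polymorphic between BY and RM, with 4 of 11 tested genes called (36.4%, against 6.58% of the other genes). Its two-sided Fisher's exact p was 0.00442, adjusted p = 0.0619, and the 4 genes were HAP1 (1.62), ENA1 (-1.30), ERC1 (0.98) and SSD1, an RNA-binding translational repressor (-0.51). Adjusted over the list alone the count was also 4. Amino acid biosynthesis had 5 of 29 genes called, or 9 adjusted over the list alone (Fisher's exact p = 0.0406, adjusted p = 0.261). They were ARO8, an aromatic aminotransferase gene (0.86), ILV6 (0.34), LEU9 (-0.56), HIS5 (-0.93) and ARG8 (-1.16). Glycolysis and fermentation had 2 of 6, PFK1 (0.25) and TDH3 (-0.21, copy TDH2), with an adjusted p of 0.261 and again 2 adjusted over the list alone. The general stress list of Msn2/4 targets had 4 of 26, or 6 adjusted over the list alone (adjusted p = 0.321). They were TKL2 (1.44), TFS1 (0.51), HSP12 (-0.34) and GSY2 (-0.33). Without the 0 min libraries TKL2 (0.65, adjusted p = 0.485) and TFS1 (0.27, adjusted p = 0.328) did not pass, and with time as a factor HSP12 did not (-0.15, adjusted p = 0.558). Ribosome biogenesis had 3 of 56, all with falling BY share, NOP53 (-2.02), MTR4 (-1.07) and LTV1 (-0.82), and adjusted over the list alone the count was 3. Without the 0 min libraries NOP53 (-0.83, adjusted p = 0.247) and LTV1 (-0.23, adjusted p = 0.803) did not pass either. Cytosolic ribosomal proteins had 3 of 51, RPS11B (0.92), RPS0A (0.37) and RPL14A (-0.50), or 2 adjusted over the list alone. All of them have near-identical copies and are uncertain, and RPS11B turned without SNVs of under 2% or over 98% BY reads (-0.10, adjusted p = 0.961). The heat shock list had 1 of 16, OPI10 (0.88), and mRNA decay machinery had 1 of 21, EDC1, an activator of decapping (0.73); both counts were 1 adjusted over the list alone. No gene was called in oxidative phosphorylation (21 tested), mitochondrial ribosomal proteins (29), the proteasome (17), cyclins and cell cycle regulators (15), ergosterol biosynthesis (13) or histones (2), and adjusted over the list alone each count was 0. The calls of ARG8, HIS5, EDC1, PFK1, RPL14A, RPS0A, RPS11B, LTV1, TFS1 and TKL2 were each lost when at least one replicate was left out, and with the replicate number as a block ARG8 had -1.12 (adjusted p = 0.0535).

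Some regulators named before the data were examined had no detectable change. The values were 0.20 ± 0.11 for IRA2, a negative regulator of Ras (adjusted p = 0.359), 0.19 ± 0.21 for AMN1, which acts in daughter cell separation (adjusted p = 0.762), and -0.08 ± 0.16 for MKT1 (adjusted p = 0.890). The feature BPL1/RPO21, which holds the gene with the rpb1-1 mutation, had 0.33 ± 0.13 (adjusted p = 0.123), and passed with limma on the slopes of the cultures (0.31, adjusted p = 0.0405). The BY share is a ratio within the libraries and does not measure loss per cell. Of the ASD genes, 48 had a share of the mRNA pool at least 2-fold higher at 42 min than at 0 min. Among them were HSP12 (5.70 on the log2 scale), TKL2 (5.05), TFS1 (4.92), GSY2 (4.83), OPI10 (2.73) and ENA1 (1.79). For any of the 48, a changed BY share need not be a difference in loss.

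The second comparison asked which genes differed between the parental alleles at 0 min. Such allele-specific expression (ASE) was called for 697 of 3030 genes tested (23.0%), with the BY allele higher for 317 and the RM allele higher for 380. Most differences were modest. For the 651 genes with a BY share between 10% and 90% over all libraries, the median size of log2(BY/RM) was 0.46, and 313 were higher from BY and 338 from RM. At the extremes, 42 genes had under 10% and 4 had over 90% BY reads. Among the strong differences, BY was higher for CIN5, YDL124W and RSB1, a sphingoid base transporter gene. RM was higher for the histone genes HHF1, HTA2 and HTB2, and for WSC2, a cell wall sensor gene, which all lie in the segments described below, where reads from RM alone need not be a difference of expression.

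CIN5 had a log2(BY/RM) of 2.85 ± 0.21 at 0 min (adjusted p = 5.90e-10), RSB1 2.41 ± 0.17, YDL124W 2.10 ± 0.08, YNL134C 2.03 ± 0.15 and THI7, a thiamine transporter gene, 1.58 ± 0.10. YNL134C was read at 1 SNV, so its value rests on that site. Other large BY-higher values among genes with a mean of at least 100 reads belonged to genes with near-identical copies and are uncertain. They were TEF2 (copy TEF1) with 7.72 ± 0.11, HXT6 (HXT7) with 4.80 ± 0.23, ENA1 with 4.53 ± 0.22, RPL7A (RPL7B) with 3.04 ± 0.14, UIP3 (PRM8) with 2.23 ± 0.19, RPS6A (RPS6B) with 2.23 ± 0.08 and RPL1A (RPL1B) with 1.60 ± 0.09. BPL1/RPO21 (IV, 203039 to 210561) had 3.95 ± 0.06, with 93.9% ± 0.287 BY reads at 0 min (SD, n = 3). Of its 27 SNVs, 15 held over 90% BY reads, 14 of them in one stretch. The neighbouring features CCT4/CRD1 and SCM3 had 49.9% and 46.2% BY reads. Reads almost only from BY in such a stretch need not be a difference of expression, and the cause was not tested. HAP1 had 0.78 ± 0.09 and MKT1 -0.32 ± 0.11 (adjusted p = 0.0346), the latter a call lost when any one replicate was left out. IRA2 (0.23, adjusted p = 0.0869) and AMN1 (-0.12, adjusted p = 0.584) did not pass, though IRA2 passed with all SNVs (0.32, adjusted p = 0.0163) and without replicate 1 (0.34, adjusted p = 0.0329).

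Most of the genes read almost only from RM lay together in 3 segments, on chromosomes II (184353 to 267336, APN2 to GRX7), IV (255604 to 307789, YDL114W/ATG20 to RPS16B) and XIV (76946 to 106695, MRX6/RIM21 to WSC2). These segments were defined after the values were seen, as stretches of at least 5 consecutive features that each held an SNV with under 10% BY reads. They held 55 features with 502 well-covered SNVs. Of these SNVs, 375 (74.7%) had under 10% BY reads and 113 (22.5%) had 30 to 70%, against 0.537% and 94.3% of the 24200 SNVs elsewhere. In the segments, 50 of 52 genes tested had an ASE call and each of these was higher from RM. Outside them 647 of 2978 were called (21.7%), 317 higher from BY and 330 from RM. Since the segments were picked by SNVs with under 10% BY reads in the same libraries, these contrasts largely follow from their definition. By the naming rule, the 10 largest RM-higher genes all lay in the segments. HHF1 (copy HHF2) had a log2(BY/RM) of -8.85 ± 0.12, HTA2 (HTA1) -8.19 ± 0.22, HTB2 -8.14 ± 0.13, WSC2 -8.74 ± 0.26, and IPP1, the inorganic pyrophosphatase gene, -9.36 ± 0.15. GET3, of the pathway that inserts tail-anchored proteins, had -7.92 ± 0.16, NTH2, a trehalase gene, -7.88 ± 0.38 and MID1/RFC3 -7.82 ± 0.23. The errors of these values are too small, since few reads were from BY, such as 4 for IPP1 and 1 for NTH2 over the 3 libraries. FLR1, a multidrug transporter gene, had 0 BY reads against 410 RM reads over the 3 libraries, at least 137-fold more from RM. LDB7 had 0 against 300, at least 100-fold, both against a floor of 3 counts over the group. These bounds are for reads at the SNVs, which in the segments need not be a difference of expression. Reads counted at several SNVs make them less certain. Of the 10 largest among genes with 10 to 90% BY reads, HIR1 (-3.03), SUB2 (-2.79), RRN6 (-2.77), PDR3 (-2.71), SRP14/UBX3 (-2.66), BUG1/SNU23 (-2.61) and MSS2/PHO2 (-2.40) also lay in the segments. RPS11B (copy RPS11A, -3.24), TIF2 (TIF1, -2.90) and YPL088W (-2.44) lay outside. With the SNVs of under 2% or over 98% BY reads left out, PDR3 no longer passed (-0.55, adjusted p = 0.175) and the sign turned for RPS11B (0.87), SUB2 (0.13), RRN6 (0.26) and MSS2/PHO2 (1e-04).

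**Figure D2:**
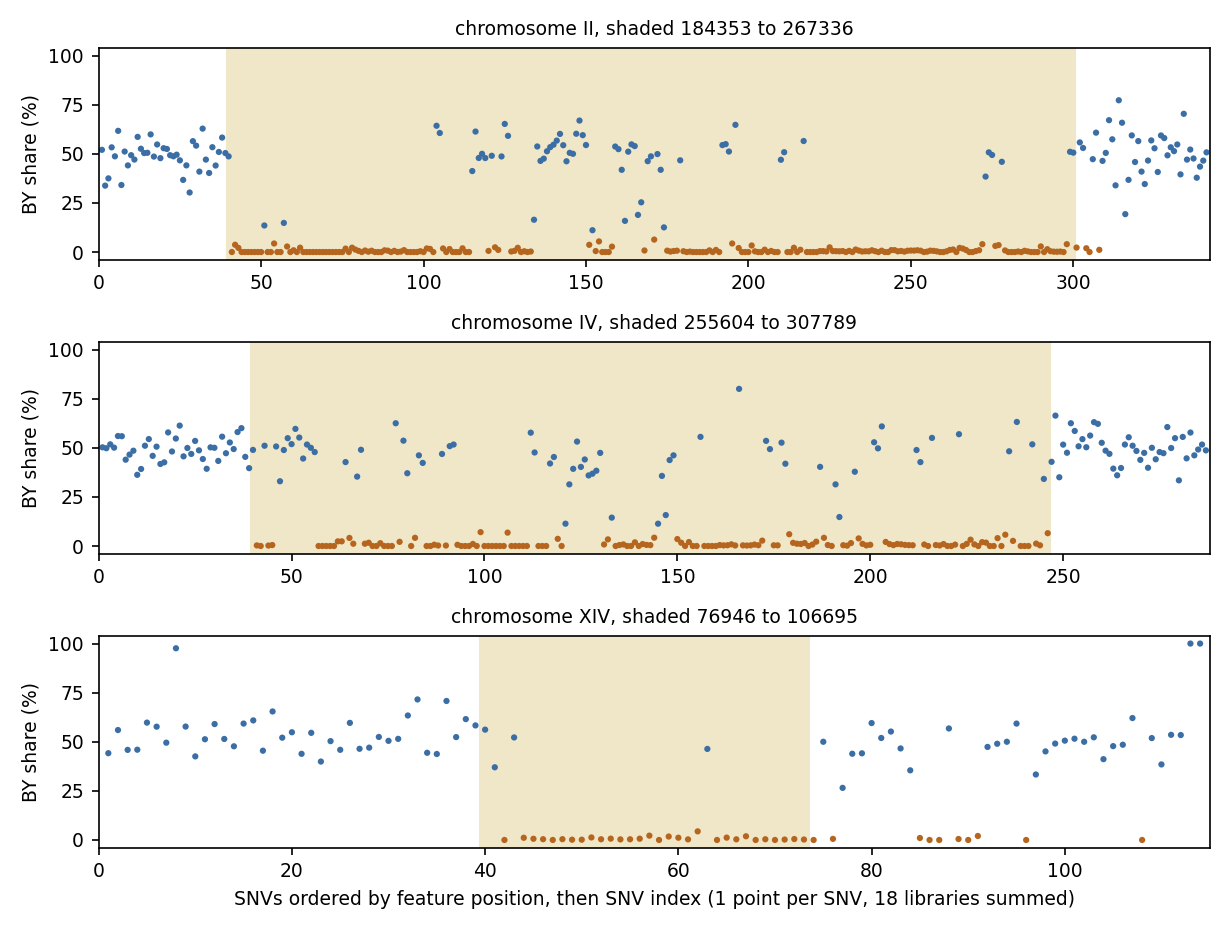
BY share in percent (vertical axis) of each SNV with at least 20 reads, all libraries summed, in order of feature position and then of SNV index (horizontal axis), around the 3 segments on chromosomes II, IV and XIV. Shading marks the segment, brown points have under 10% BY reads and blue points the rest. In the shaded parts 375 of 502 SNVs have under 10% BY reads, between others near 50%, and on chromosome XIV more such SNVs follow the shaded part.

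Among the fixed lists, that of heat shock genes had 5 BY-higher and 2 RM-higher of 15 tested. Examples were the disaggregase gene HSP104 (0.37), HSP82 (0.64, copy HSC82) and SSA1 (0.70, copy SSA2); SSA1 no longer passed without SNVs of under 2% or over 98% BY reads (0.15), and HSP78 (0.76) did not pass in DESeq2 (adjusted p = 0.394) or without replicate 3 (adjusted p = 0.0923). Cytosolic ribosomal proteins had 15 and 16 of 56, nearly all with near-identical copies, with RPL5 at 0.47 among those without one. The general stress list had 3 and 4 of 18, such as SOL4 (1.92) and UBI4 (-0.29), and ribosome biogenesis 6 and 4 of 63, such as CIC1 (0.55) and RRP5 (-0.35). Oxidative phosphorylation had 4 and 6 of 22, the proteasome 2 and 5 of 17, amino acid biosynthesis 1 and 5 of 30, with HIS5 at -1.22, and ergosterol biosynthesis 4 and 3 of 13, with ERG11, the lanosterol demethylase gene, at -0.995. mRNA decay machinery had 2 and 4 of 25, with the decapping activator PAT1 at 0.51. The polymorphic regulators had 4 and 3 of 12, such as FLO8, a transcription factor of flocculation (-1.48), which did not pass without replicate 2 (adjusted p = 0.055). Mitochondrial ribosomal proteins had 0 and 3 of 30, histones 0 and 3 of 5, cyclins and cell cycle regulators 0 and 2 of 17, and glycolysis 2 and 1 of 6. Of the RM-higher genes in these lists, all 3 histone genes and 1 gene each of mitochondrial ribosomal proteins (MRPL10), ribosome biogenesis (UTP20), the proteasome (RPN6), cell cycle regulators (PCL1) and mRNA decay machinery (CAF40) lay in the segments. These counts were not tested against each other.

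The third comparison asked how the composition of the mRNA pool changed after the shift. Stress genes gained share and ribosome biogenesis genes lost it, most of them by several fold. At 42 min, 1057 of 2840 genes were higher than at 0 min, 1109 were lower and 674 did not pass, and the change was at least 2-fold up for 489 and down for 660. Libraries hold shares of the pool and not amounts per cell, so a higher share means only that a transcript was lost more slowly than the rest or was made anew. Scaled to the cytosolic ribosomal protein genes in place of TMM (trimmed mean of M-values), the median change of all genes moved from -0.05 to 0.92 on the log2 scale, and 1833 genes were higher and 437 lower. Changes below are relative to the TMM scaling.

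HSP26/YBR072C-A, a feature with the small heat shock protein gene HSP26 (II, 382030 to 383021), rose most, by 9.25 ± 0.33 on the log2 scale (adjusted p = 6.07e-14). Its mean went from 11.9 to 7439 CPM (reads scaled to the same library total). SSA4, a heat-inducible Hsp70 gene, rose by 6.72 ± 0.30, from 12.7 ± 2.64 to 1391 ± 462 CPM (SD, n = 3), and SSE2, an Hsp110 gene, by 5.94 ± 0.19. With time as a linear term SSA4 did not pass (2.36, adjusted p = 0.0988). PHM7 rose by 8.87 ± 0.87, YRO2 by 6.92 ± 0.31, ALD3, an aldehyde dehydrogenase gene with the near-identical copy ALD2, by 6.87 ± 0.86, and SOL4, a 6-phosphogluconolactonase gene, by 6.27 ± 0.49. The cell wall genes YGP1 and SPI1 rose by 6.24 ± 0.21 and 6.14 ± 0.73, and GIP2, a regulator of protein phosphatase Glc7, by 6.06 ± 0.55. DBP2 changed by -8.25 ± 0.36, from 470 ± 48.2 to 1.24 ± 1.23 CPM. PUF6 changed by -5.94 ± 0.36, NOG1 by -5.88 ± 0.34, HCA4 by -5.46 ± 0.25, EBP2 by -5.38 ± 0.30, MTR4 by -5.36 ± 0.23 and NSR1 by -5.07 ± 0.30, all of them genes of ribosome assembly or RNA processing. RPA135 and RPA34, subunits of RNA polymerase I, changed by -5.41 ± 0.36 and -5.27 ± 0.25, and the feature INA1/PUN1/YLR415C by -5.41 ± 0.36. Among the genes named in advance, IRA2 changed by 1.45 ± 0.18 and LYS2 by -1.48 ± 0.22, but IRA2 did not pass with time as a linear term (0.61, adjusted p = 0.152), nor LYS2 with the ribosomal protein scaling (-0.55, adjusted p = 0.0511). HAP1 changed by -0.46 ± 0.11 but was higher with the ribosomal protein scaling (0.53). AMN1 (-0.29, adjusted p = 0.0802), BPL1/RPO21 (0.20, adjusted p = 0.0883) and MKT1 (-0.02, adjusted p = 0.953) did not pass. With the ribosomal protein scaling all 3 were higher, AMN1 by 0.67 (adjusted p = 0.00399), MKT1 by 0.95 (adjusted p = 1.04e-04) and BPL1/RPO21 by 1.19 (adjusted p = 2.58e-05). AMN1 was lower with a minimum of 100 reads (-0.47, adjusted p = 0.00860) and with the deepest SNV (-0.52, adjusted p = 0.0453). BPL1/RPO21 was higher with the replicate block (0.20, adjusted p = 0.0205) and with time as a linear term (0.31, adjusted p = 0.0236).

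All 26 general stress genes tested rose, with a median of 4.67, led by ALD3 (6.87), SOL4 (6.27) and YGP1 (6.24); the catalase gene CTT1 had 5.89 and HSP12 5.70. The camera set test of limma gave an adjusted p of 5.85e-13, and adjusted p = 0.200 with an estimated correlation between genes. All 16 heat shock genes rose as well, with a median of 2.59, led by SSA4 and SSE2, with HSP78 at 3.40, HSP82 at 3.07 and HSP104 at 2.93 (adjusted p = 6.43e-09, and adjusted p = 0.232 with an estimated correlation). All 56 ribosome biogenesis genes fell, with a median of -4.33, led by RRP12 (-8.17), SSF1 (-7.09) and LCP5 (-6.30). Their adjusted p was 1.34e-16, and adjusted p = 0.200 with an estimated correlation. Adjusted over the list alone, these counts were again 26, 16 and 56, and all 3 medians kept their sign with the ribosomal protein scaling (5.66, 3.57 and -3.41).

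**Figure D3:**
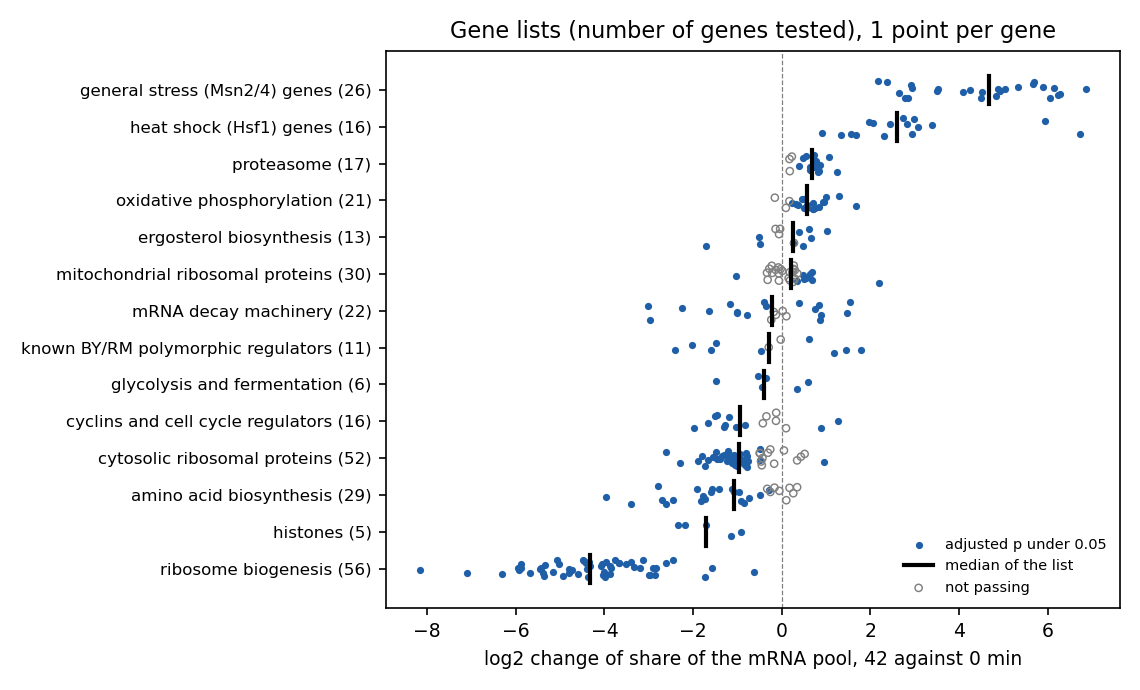
Log2 change of the share of the mRNA pool at 42 min against 0 min (horizontal axis, TMM scaling) for each tested gene of 14 fixed lists (vertical axis, number of genes tested in parentheses). Filled points passed an adjusted p of 0.05, open points did not, and the black bar is the list's median. General stress genes lie around a median of 4.67 and ribosome biogenesis genes around -4.33, and with the ribosomal protein scaling, which sets the ribosomal protein list near 0 by construction, the medians of 4 other lists turn positive, those of cell cycle regulators, decay machinery, glycolysis and polymorphic regulators.

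Oxidative phosphorylation genes rose for 18 of 21, with a median of 0.57, such as SDH2 (1.68) and COX5B (1.28), at an adjusted p of 2.16e-04 (adjusted p = 0.268 with an estimated correlation). Proteasome genes rose for 14 of 17, with a median of 0.68, such as PRE5 (1.24) and RPN2 (1.06), at an adjusted p of 6.22e-04 (adjusted p = 0.422 with an estimated correlation). Cytosolic ribosomal protein genes fell for 39 of 52 and rose for 1, with a median of -0.96, such as RPL9A (-2.62) and the single riser RPS30A (0.94), at an adjusted p of 3.40e-06 (adjusted p = 0.444 with an estimated correlation). That list's name pattern also took in RPP1 (-2.28), a subunit of RNase P. Amino acid biosynthesis genes fell for 21 of 29, with a median of -1.07 that was -0.70 without replicate 3, such as PRO1 (-3.96) and LYS4 (-3.41), at an adjusted p of 6.22e-04 (adjusted p = 0.302 with an estimated correlation). Histone genes fell for 5 of 5, with a median of -1.70, among them HTB2 (-2.33) and HTA2 (-2.18), at an adjusted p of 0.00424 (adjusted p = 0.130 with an estimated correlation). Adjusted over the list alone the counts were again 18, 14, 39 with 1, 21 and 5. With the ribosomal protein scaling the medians were 1.59 for oxidative phosphorylation, 1.67 for the proteasome, -0.13 for amino acid biosynthesis and -0.73 for histones.

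The other lists went both ways and had no list-wide call. Cyclins and cell cycle regulators fell for 9 and rose for 2 of 16 (median -0.93, or 0.03 with the ribosomal protein scaling, adjusted p = 0.158). The G1 cyclin gene CLN2 (-1.98) and CDC20 (-1.67) fell, and CLN3 (1.26) and SIC1 (0.88) rose. mRNA decay machinery fell for 10 and rose for 7 of 22 (median -0.21, or 0.76 with that scaling, adjusted p = 0.713). The exosome subunit genes RRP40 (-3.01), CSL4 (-2.98) and DIS3 (-2.25) fell, and the RNA-binding protein genes JSN1 (1.54) and NGR1 (1.47) rose. Mitochondrial ribosomal proteins rose for 8 and fell for 1 of 30, or 7 and 1 adjusted over the list alone (median 0.21, or 1.19 with that scaling and 0.11 without replicate 3, adjusted p = 0.343), with MRP8, a gene of unknown function that the list's name pattern takes in, at 2.20. Ergosterol genes rose for 6 and fell for 3 of 13 (median 0.26, or 1.19 with the other scaling, -0.01 without replicate 1 and 0.07 without replicate 2, adjusted p = 0.649), among them ERG28 (1.02) and ERG3 (-1.71). Glycolysis genes fell for 4 and rose for 2 of 6 (median -0.41, or 0.59 with the other scaling, adjusted p = 0.713), among them PDC5 (-1.49) and TDH3 (0.60). The polymorphic regulators fell for 5 and rose for 4 of 11 (median -0.29, or 0.67 with the other scaling and -0.17 without replicate 3, adjusted p = 0.713). For these lists other than mitochondrial ribosomal proteins, counts adjusted over the list alone were the same. Of the haploid-specific and mating genes, the markers of any haploid cells left in the culture, 8 lay in single-gene features and none passed the read minimum.

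The last comparison set the allelic difference at 0 min against the later change, to ask whether the more abundant allele was also the more slowly lost one. The ASD change was fitted without the 0 min libraries for this. Of 41 genes called in both, 26 had opposite signs, so that the BY/RM ratio moved towards the other allele, and 15 had the same sign, or 7 and 6 with the deepest SNV. These counts cover called genes only. CIN5, EXG1, YDL124W and YPL088W moved towards equal alleles or past them, and HAP1 moved further towards BY. Of the ASD genes also tested for ASE, 84 of 183 (45.9%) had an ASE call, against 23.4% of all genes tested for both; these 2 sets of calls share the 0 min libraries, and depth favours both.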

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

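The tests given in this part were chosen after the data were seen. The SNVs outside the series table held unequal allelic reads that the comparisons above did not use, and the rule that left these SNVs out is not known. Among 131 features with SNVs only outside that table, 32 of 65 tested had unequal alleles at 0 min, 20 higher from BY and 12 from RM, and 10 of 55 tested had a changing BY share. The largest of the latter were HPF1, a cell wall mannoprotein gene (2.51), CSS1 (2.56) and, with falling BY share, GRE2, a methylglyoxal reductase gene (-0.98). HPF1 and CSS1 had log2(BY/RM) at 0 min of -2.29 and -5.23. Of the 1312 such SNVs with over 100 reads, 230 had over 98% BY reads and 32 under 2%, against 41 and 259 of 17368 SNVs in the series table. BFR1 (100% BY) and the feature BLI1/FBA1 with the aldolase gene (99.9%) were among features read almost only from BY there. Both are counted among the 20 higher from BY. Such reads need not be a difference of expression, and faulty or poorly mapped SNVs were not tested for here.

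A small set of genes changed direction between 6 and 42 min, each compared with 0 min. There were 3 genes higher at 6 min and lower at 42 min, RPI1 (0.62 then -0.77), YAR1 (0.47 then -0.64) and FSH3 (0.52 then -0.50). A further 7 were lower at 6 min and higher at 42 min, namely RPM2, a feature with a mitochondrial RNase P subunit gene (-0.50 then 1.03), RLM1, a transcription factor of cell integrity signalling (-0.81 then 0.63), HMG1, an HMG-CoA reductase gene (-0.45 then 0.62), PTR2 (-0.41 then 0.60), SNT1 (-0.30 then 0.47), SLF1 (-0.42 then 0.42) and EFM2/HSM3 (-0.49 then 0.42). These directions are relative to the TMM scaling.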

How the results depend on the processing

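The alternatives with the SNVs outside the series table, the deepest SNV of each feature, single-gene features, a BY share of 10 to 90%, SNVs split into 2 parts and the shallow library left out were added after the data were seen; the rest were planned. Thinning SNVs to 150 bp was not run, as SNV positions were not used here, and the deepest SNV stands in for it. Over 175 values of named genes and their alternatives, 2231 of 2458 values kept direction and side of the threshold, 197 kept direction but no longer passed, 8 kept direction and newly passed, and 22 turned, 10 of these for genes that had not passed. Unless a reason is given, the cause was not tested.

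Of the 188 ASD genes (102 RM faster, 86 BY faster), DESeq2 called 120 (61 RM faster), all among the 188. Calls were fewer without the 42 min libraries, 115 (62 and 53), and without those of 0 min, 87 (48 and 39). With 1 replicate left out they were 99 to 129 (50 to 68 and 49 to 61). The deepest SNV alone, with fewer reads, gave 42 (18 and 24), and 9 of the 151 ASD genes it could test had the opposite sign. The shallow library left out gave 188, of which 186 were shared. RPS11B turned without extreme SNVs (-0.1001), and MTR4 with its deepest SNV (0.2924). Genes without a call turned as well, AMN1 (-0.064) and MKT1 (0.3624) without the 42 min libraries, IRA2 (-0.0131) with time as a factor, and BPL1/RPO21 (-0.509), AMN1 (-0.0075) and IRA2 (-0.0181) with the deepest SNV.

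Of the 697 ASE genes (317 BY higher, 380 RM higher), DESeq2 called 228 (89 and 139), a fit without library terms 298 (120 and 178), the deepest SNV 392 (173 and 219), and 428 to 561 (191 to 253 and 237 to 308) were called with 1 replicate left out. The fit on 18 libraries called 987, 489 higher from BY and 498 from RM. With all SNVs the count was 807 and its balance changed sides, 419 higher from BY and 388 from RM. Without extreme SNVs the sign turned for RPS11B (0.8675), SUB2 (0.1263), RRN6 (0.2608), PFK2 (0.0337), SSF1 (-0.0833) and MSS2/PHO2 (1e-04); with the deepest SNV it turned for SSF1 (-0.081) and BUG1/SNU23 (0.2265). Over all ASE genes, 43 of 616 tested with the deepest SNV and 10 of 659 without extreme SNVs had the opposite sign.

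For abundance, the minimum of 100 reads left fewer genes and 602 higher and 636 lower, the deepest SNV 692 higher, and leaving out 1 replicate 928 to 964 higher and 991 to 1045 lower. The ribosomal protein scaling gave 1833 higher and 437 lower, since it shifts all genes up, and turned TPI1 (0.4286), HAP1 (0.5311), AMN1 (0.6705) and MKT1 (0.951). MKT1, which had not passed, also turned in the fit on 6 libraries (0.0022) and ran from -0.0765 to 0.048 with 1 replicate left out. With time as a linear term SSA4, HSP78, TDH3 and IRA2 no longer passed. Of the 8 lists called, 0 were called with an estimated correlation.

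The change of the BY share was -0.052 percentage points without extreme SNVs, 0.604 with all SNVs and 0.48 with the deepest SNV.

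With the replicate block, which pairs the libraries of a culture, 184 ASD genes, 1086 higher and 1155 lower genes and 8 lists were called, the lists at the preset correlation only, since with an estimated one and the block the lowest adjusted p was 0.140. Among named genes it changed only ARG8 and BPL1/RPO21, as given above.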

Other observations

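Of the tests in this part, those on the RM-only segments and on the early rise of stress genes were chosen after the result was seen. The bounds of those on the ASD calls were set before these tests were run. The count of 188 ASD genes was already known then, since the bound for reads counted at more than 1 SNV was taken from it. Outside the segments, a few more genes were read almost only from one allele. SAM3 and SAM4, neighbouring genes of S-methylmethionine metabolism on chromosome XVI, had 0% and 4.38% ± 2.73 BY reads at 0 min (SD, n = 3), the latter uncertain because of its near-identical copy YMR321C. POS5, a mitochondrial NADH kinase gene read at 1 SNV, had 0 of 137 reads from BY, which by counting alone allows a share of up to 2.19%. SAM3 had 0 of 153, which allows up to 1.96%. A fault of the single SNV of POS5 was not tested for. RPL27B had 0.644% ± 0.517 BY reads, and CTR3, a copper transporter gene, 3.12% ± 1.00 at 1 SNV. In the other direction, the feature ERG9/CTF8, with the squalene synthase gene ERG9, had 0 of 215 reads from RM, which allows up to 1.40%.

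The pool changed early. At 6 min, 499 genes were already higher and 492 lower than at 0 min. The heat shock list had by then reached 75.2% ± 8.97 of its 42 min difference from the median gene (SD, n = 3), ribosome biogenesis 34.2% ± 6.53, the proteasome 18.0% ± 8.59 and oxidative phosphorylation 7.52% ± 13.3. ASD genes were found among genes of each kind of change. They made up 7.46% of 1045 genes higher at 42 min, 6.47% of 1098 lower and 5.87% of 665 that did not pass (two-sided Fisher's exact p = 0.396 for higher against lower). The median gene of these groups had 170, 91.7 and 82.9 reads per library. Depth favours calls and was not adjusted for, so equal shares are not shown.

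In the segments of chromosomes II, IV and XIV, 375 SNVs had under 10% BY reads, and in each culture the BY share over them was under 1%. Scattered false or poorly mapped SNVs are argued against, as the longest stretch of consecutive features with such an SNV held 26, and 1000 shuffled orders gave at most 4. Loss of the BY copy of whole segments is argued against by the 22.51% of SNVs at 30 to 70% BY reads between them, or 22.6% without the first and last features. By segment this share was 19.5% on II, 28.5% on IV and 8.82% on XIV, the last from only 3 of 34 SNVs. The stretch from HTA2 to UGA2 on II held no such SNV, so loss of shorter stretches is not weighed by this value. The test for sequence of another strain in the BY parent decides nothing, since 97.211% of SNVs in the segments fell in one of the 2 classes but so did 94.8% elsewhere, and the origin of the segments stays open. The segment on chromosome IV lies near RPO21, where 15 of 27 SNVs had over 90% BY reads, and neither parent was sequenced here on its own.

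The ASD calls were weighed against chance and artefacts of counting. Over 100 orders of the times within cultures, the real one included, 1 gave as many genes, the real order with 188. The highest other order gave 31. Chance is thus argued against as the source of the count as a whole. The orders weigh only that count, so chance is not excluded for single genes among the calls. Single faulty SNVs are argued against for genes that could be tested in both parts of their SNVs. Of 89 genes called from the left part, 87 had the same sign in the right part. Of 85 called from the right part, 82 had it in the left, 97.126% over both directions, and 43 genes were called in both parts. A read that covers SNVs of both parts counts in both, which can raise this agreement. Genes with 1 SNV, such as GPP1, were not in this test. Reads counted at more than 1 SNV are argued against as the source of the calls, because the other orders keep such reads and gave a median of 0 genes. What stays open for the calls as a set is a biological difference in decay between the alleles, or unequal new transcription from them after the shift. The one could not be separated from the other here.

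The early rise of stress genes was weighed against loss alone. If each transcript were lost at a constant rate and none were made, differences between genes would grow linearly and reach 14.3% of their 42 min size at 6 min. The general stress list reached at least 31.21% in each culture (mean 44.8% ± 11.8, SD, n = 3), which argues against loss at constant rates alone. New transcripts made after the shift may account for it, but the value that bears on this, a 64.371-fold higher share of HSP26/YBR072C-A at 6 min, needs amounts per cell to be read, since with no new transcripts it would mean that 1.55% of the pool was left. Changes in stability after the shift stay open as well, and none of these was separated.

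For the other counts, the splits that were run are too few to weigh chance. Of 10 splits of the 6 libraries of 0 and 42 min, fitted alone, 1 gave as many genes, the real one with 2076, and the highest other gave 0. Of 4 ways to swap the alleles in the 3 libraries of 0 min, 1 gave as many, the real one with 697, and the highest other gave 0.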
